A study of Homo sapiens with 10 samples.

How the data were processed

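RNA was measured by sequencing in 10 libraries of human acute myeloid leukemia (AML) cells that came from patients and were kept in ex vivo culture. The labels distinguish 2 donors, called donor A and donor B here, and an agent, either cytarabine (AraC) or its vehicle, dimethyl sulfoxide. Donor A has 3 vehicle and 3 AraC libraries (1000 nM for 24 h), and donor B has 2 vehicle and 2 AraC libraries (100 nM for 72 h). The culture time of the vehicle libraries is not in the labels. Donor, dose and time change together, so they cannot be told apart. The labels number the replicates but do not say that they are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

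Each library has a file of TPM (transcript abundance scaled to a total of 1000000) per gene symbol, deposited by the authors, and the values of each file sum to 1000000. Libraries were made with the TruSeq RNA kit, per the labels' protocols, and STAR (no version given) and the human genome build hg19 are named in the submitters' processing notes. The read counter, the gene annotation and the use of strand are not given in the sources used here. The files list 23250 gene symbols and no mitochondrially encoded genes. Removing 102 Y-linked and X-inactivation genes left 23148. No hg19 annotation was at hand, so genes are named by the symbols of the files, several of them older symbols such as IL8 (CXCL8), and no positions are given. Without a known counting rule, values of genes with near-identical copies or overlapping neighbours are uncertain: histone and tryptase genes, HSPA1A and HSPA1B, NCF1, MHC class II genes, ribosomal protein genes with pseudogenes, and small nucleolar RNA and microRNA genes inside host genes. The series' design text speaks of primary xenografts, and whether mouse reads were removed is not given in the sources used here.

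TPM carries no depth by itself. To recover whole reads, the values of a gene across libraries were taken as whole multiples of a common step. With these steps 100% of the values lay within 0.02 reads of a whole number. The step of each gene was chosen to fit its own values, so this share is no test of the recovery. For genes with reads in few libraries the step is uncertain. The recovered depth was 29269061 to 34108840 reads per library. At this depth counting error is small for genes at several TPM. Precision is limited by the number of libraries.

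Values were analysed as log2(TPM + 1). A fold change on this scale understates the change of genes with low values. Genes with a TPM of 1 or more in at least 2 of the 10 libraries were kept, which left 14401. The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend) with 1 mean for each of the 4 groups, so that all libraries share the estimate of the spread, with 6 residual degrees of freedom. The comparisons were AraC against vehicle in donor A, the same in donor B, and the difference of these changes (donor B minus donor A). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

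Gene lists for 33 pathways and cell types were fixed before the data were examined, and the 32 with at least 3 measured members were tested. They were p53 targets, DNA replication and E2F targets, G2/M and mitosis genes, replication-dependent histones, secreted senescence-associated genes, cell-cycle inhibitors and senescence regulators, NF-kappaB targets, type I interferon response genes, granulocyte and monocyte maturation genes, granule genes of immature myeloid cells, stem and progenitor genes, cytarabine uptake and metabolism genes, DNA damage checkpoint and repair genes, apoptosis regulators of the BCL2 family, MYC targets, oxidative phosphorylation genes, cytosolic ribosomal protein genes, lysosome and autophagy genes, cholesterol synthesis genes, hypoxia and glycolysis genes, unfolded protein and integrated stress response genes, MHC class II and class I genes, immediate-early genes, heat shock genes, and markers of T and NK cells, B and plasma cells, erythroid cells, megakaryocytes and platelets, endothelium, fibroblasts and stroma, and mast cells, basophils and eosinophils. The list of mitochondrially encoded genes had no measured member. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, and again with the correlation estimated per list. Limma's fry tested whether a list's genes move, on balance, in one direction, which compares the list with no other genes. A member is said to have risen or fallen where it was called over all genes tested, and counts adjusted over the list alone are given where they differ.

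The genes named in the text were fixed by a rule: per donor, the 10 largest rises and the 10 largest falls among called genes whose AraC libraries all lay on the same side of all vehicle libraries and whose mean TPM was 5 or more in the higher group; per list, up to 4 called members with the smallest p, or up to 2 if none was called; 11 genes always named (CDKN1A, MDM2, LMNB1, GLB1, MKI67, RRM2, DCK, SAMHD1, ATR, CEBPA and CD34); and the 5 most positive and 5 most negative differences between donors. A gene named outside this rule is marked as chosen after its values were seen.

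The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, median-ratio scaling, quantile normalization, leaving out the 20 most abundant genes, eBayes without trend and robust eBayes, each donor alone, the replicate number as a block, a minimum change of 2-fold, the other list tests and leaving out each library. Limma's voom on the recovered reads and leaving out small RNA genes were added after the values had been seen. The code was tested on simulated libraries drawn around the real vehicle means with the real spreads, 14401 genes and 200 changed genes. In donor A's comparison it recovered 73.8% of genes changed by 0.5 on the log2 scale, 98.8% at 1 and 100% at 2; in donor B's, 60% at 0.5, 93.8% at 1 and 100% at 2. Of the calls, 8.25% in donor A's comparison and 5.78% in donor B's were of unchanged genes. The changed genes were drawn only from those above a minimum vehicle value, and the spread was simulated independently for each gene. Far more genes were called in the real data than were changed here, so these shares need not hold there.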

Results

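The study asked what AraC does to gene expression in AML cells that survive it in culture, as its title names a transient senescence-like state. AraC is a cytidine analogue that is built into DNA and stops replication. Gene expression was measured in 10 libraries: 3 vehicle and 3 AraC libraries of donor A (1000 nM, 24 h) and 2 vehicle and 2 AraC libraries of donor B (100 nM, 72 h). Depth ran from 29269061 reads in donor A AraC replicate 1 to 34108840 in donor A vehicle replicate 1. Within groups, the log2 values of replicates correlated across genes with Pearson's r of 0.995 to 0.997, and every pair differed by more than counting error (chi-square per degree of freedom of 2.51 to 34.6), so no library was counted as a copy of another. Between 11987 and 13219 genes per library reached a TPM of 1.

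In donor A the largest rise after AraC was in ENPP2. This gene, which encodes the secreted enzyme autotaxin, rose to 180.3 ± 3.88 TPM (mean ± SD, n = 3), a log2 change of 3.50 (SE 0.07). The receptor tyrosine kinase gene AXL rose by 3.26 (SE 0.07), and the complement receptor gene C3AR1 rose from 43.1 ± 2.56 to 311.2 ± 3.63 TPM. GJB2 (a gap junction protein), CLEC7A (the beta-glucan receptor of myeloid cells), UCA1 (a long noncoding RNA), C1orf186, GNLY (a cytotoxic granule protein), LPAR5 and LBH completed the 10 largest rises, with log2 changes of 2.68 to 2.94. The largest falls were smaller. The constitutive chaperone gene HSPA8 fell from 1878 ± 112 to 700.9 ± 64.2 TPM, CDC20, which activates the anaphase-promoting complex, fell from 230.2 ± 5.80 to 95.3 ± 3.26 TPM, and CHAC1, ECE2, SLC27A4, CCDC86 and the noncoding LOC92659 fell by 1.24 to 1.47. The short RNAs SNORD77, SNORA80B and SNORD35A also fell, but such short genes are poorly measured in these libraries. In all, limma called 5540 genes higher and 2358 lower of 14401 tested, 638 and 50 of them by at least 2-fold. At an unadjusted p under 0.05 there were 8602 genes. The median gene was 0.12 higher on the log2 scale, and the split depends on this shift: with median-ratio scaling it was 4524 higher and 3535 lower, and with quantile normalization 3754 higher and 4213 lower. Small changes are to be read relative to it. Camera called 17 of 32 gene lists in donor A and 22 in donor B. The 9 other ways to split donor A's 6 libraries into groups of 3 called 6 to 17 lists (and 0 to 1 genes). Each of those splits mixes vehicle and AraC libraries in both groups and so keeps part of the treatment contrast. They therefore cannot show how many lists camera calls without a treatment difference. As camera's calls also depend on the correlation setting, each list below is described by its members first.

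Most DNA replication genes rose in donor A, and the G2/M genes went both ways. Of 55 DNA replication and E2F target genes 45 rose and 3 fell, with a median log2 change of 0.33. The thymidine kinase gene TK1 rose from 154 ± 8.12 to 281 TPM, the ribonucleotide reductase subunit gene RRM2 from 219.4 ± 5.44 to 347.1 ± 4.33 TPM, thymidylate synthase TYMS by 0.60 (SE 0.04) and cyclin E2 (CCNE2) by 0.91 (SE 0.06). Camera called this list up (adjusted p = 8.2e-05), and the call was lost with an estimated correlation (adjusted p = 0.42). Of 44 G2/M and mitosis genes 16 rose and 8 fell, and the list was not called (camera adjusted p = 0.70). Its median (0.13) and mean (0.06) were above 0 while camera, which compares with all other genes, had it down. CDC20 fell by 1.26, cyclin B1 (CCNB1) by 0.47 and CKS2 by 0.57, while CDK1 rose by 0.35 (SE 0.04). The proliferation marker MKI67 was at 74.8 ± 24.7 TPM in vehicle and 91.9 ± 6.29 TPM after AraC, which did not pass (adjusted p = 0.18), but passed without vehicle replicate 1 (log2 change 0.57, adjusted p = 0.017). Of 38 p53 target genes 17 rose and 8 fell, and camera did not call the list against other genes (adjusted p = 0.99), while fry, which compares with no other genes, called it up (adjusted p = 0.0055). With quantile normalization 13 rose and 14 fell. TP53INP1 rose by 1.69 (SE 0.09), BTG2 by 1.26 (SE 0.08) and DDB2, a damage recognition gene, by 0.76 (SE 0.04), and SESN2 fell by 0.87 (SE 0.07). CDKN1A, which encodes the cell-cycle inhibitor p21, was at 90.4 ± 2.17 TPM in vehicle and 105.3 ± 4.92 TPM after AraC (log2 change 0.22, SE 0.04). Its call was lost with median-ratio scaling (0.10, adjusted p = 0.065). MDM2, the p53 ubiquitin ligase, rose by 0.33 (SE 0.07). No replication-dependent histone gene of 23 rose and 4 fell (2 adjusted over the list alone), among them HIST1H2BK by 0.73 and HIST1H1C by 0.43. Camera called the list down (adjusted p = 0.0049; adjusted p = 0.15 with an estimated correlation), and with quantile normalization 13 fell. DNA damage checkpoint and repair genes rose in 24 and fell in 6 of 54 members and were not called (camera adjusted p = 0.67). With median-ratio scaling 18 of them rose and 15 fell, and with quantile normalization 20 rose and 12 fell.

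Growth and protein-folding genes fell in donor A. Of 44 MYC target genes 39 fell (40 adjusted over the list alone) and 2 rose, with a median of -0.60. The ribosome biogenesis genes RRP9 and NOP16 fell by 1.14 and 1.10 (SE 0.05 each), and MYC itself went from 850 to 435 TPM (log2 change -0.97, SE 0.09). The list was called with the preset (camera adjusted p = 1.9e-21) and with an estimated correlation (adjusted p = 0.029). Of 16 heat shock genes 13 fell and 1 rose, with a median of -0.62. HSPA8 by 1.42 (SE 0.07) and CHORDC1 by 1.20 (SE 0.06) fell, and the collagen chaperone gene SERPINH1 rose by 0.97. This list too held with an estimated correlation (adjusted p = 0.018; camera adjusted p = 2.5e-09 with the preset). Of 49 oxidative phosphorylation genes 33 fell (35 adjusted over the list alone) and 1 rose, by small amounts. The falls were 0.56 for SDHB and 0.50 for CYC1 (list median -0.24, camera adjusted p = 1.6e-10), and this call was lost with an estimated correlation (adjusted p = 0.37). Cytosolic ribosomal protein genes had 3 rises and 4 falls among 44 members (none adjusted over the list alone). Their camera call (adjusted p = 0.0059) was lost with an estimated correlation (adjusted p = 0.68), with quantile normalization (adjusted p = 0.68), without vehicle replicate 2 (adjusted p = 0.38) and without AraC replicate 2 (adjusted p = 0.22).

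Genes of myeloid maturation, interferon response and MHC class II rose in donor A, and so did markers of other cells: the medians were 0.83 for T and NK cell markers, 0.84 for fibroblast and stromal markers and 0.62 for B and plasma cell markers. The last list was not called, and the calls of the first 2 were lost with an estimated correlation (adjusted p = 0.12 and 0.39). Of 43 granulocyte and monocyte maturation genes 37 rose (38 adjusted over the list alone) and 1 fell, with a median of 0.76. The integrin gene ITGAM (CD11b) rose by 2.24 (SE 0.07), the endotoxin co-receptor gene CD14 from 23.5 to 79.2 TPM, and the Fc receptor gene FCGR2A and TREM1 by 1.72 and 1.86. The lysozyme gene LYZ fell by 0.31 from 22148 TPM, a call that was lost with quantile normalization. The list was called by camera (adjusted p = 2.5e-09; adjusted p = 0.018 with an estimated correlation). Of 47 type I interferon response genes 42 rose (43 adjusted over the list alone) and none fell, with a median of 0.81, including PLSCR1, CMPK2 and IFI35 with rises of 1.15 to 1.51 (camera adjusted p = 4.8e-10; adjusted p = 0.080 with an estimated correlation). Of 11 MHC class II genes 10 rose, such as HLA-DRA from 12.8 to 32.9 TPM (camera adjusted p = 2.7e-04; adjusted p = 0.049 with an estimated correlation). Granule genes of immature myeloid cells rose in 10 and fell in 2 of 19 members, and stem and progenitor genes rose in 16 (15 adjusted over the list alone) and fell in 1 of 42. Neither list was called (camera adjusted p = 0.21 and 0.16). With quantile normalization camera called the granule list up (adjusted p = 0.015), with 10 rises and no fall. Stem and progenitor genes then rose in 13 and fell in 9, without a call (adjusted p = 0.18). The myeloid transcription factor gene CEBPA rose by 0.70 (SE 0.06). CD34, a progenitor marker, went from 0.957 to 1.59 TPM, and this call was lost with quantile normalization (adjusted p = 0.81). MHC class I genes rose in 9 and fell in 1 of 15 members and were not called (camera adjusted p = 0.13).

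Secreted and lysosomal genes rose as well in donor A. Of 44 secreted senescence-associated genes 29 rose and 3 fell, with a median of 0.53. IGFBP4 rose from 10.4 to 54.3 TPM (log2 change 2.28, SE 0.06), the chemokine genes IL8 and CCL5 by 1.49 and 0.83, and the cathepsin gene CTSB by 0.74 (camera adjusted p = 2.6e-04; adjusted p = 0.39 with an estimated correlation). Of 41 NF-kappaB target genes 28 rose and 5 fell, among them BCL2A1, CCL20 and MAP3K8 with rises of 1.30 to 1.68 (camera adjusted p = 0.0045; adjusted p = 0.42 with an estimated correlation). Cell-cycle inhibitors and senescence regulators rose in 19 and fell in 4 of 32 members. The rises included ID2 (1.86), ID1 (1.79), YPEL3 (1.35) and the lysosomal fucosidase gene FUCA1 (0.82). Camera called the list up (adjusted p = 0.028), and the call was lost with an estimated correlation (adjusted p = 0.42). The list mixes cell-cycle inhibitors with genes that need not move with them, such as LMNB1, so its direction is no measure of senescence. Lysosome and autophagy genes rose in 33 and fell in 1 of 44 members (camera adjusted p = 4.4e-05; adjusted p = 0.26 with an estimated correlation), with GABARAPL1 and WIPI1 up by 1.58 and 1.62. GLB1, the source of senescence-associated beta-galactosidase activity, rose from 129.3 ± 1.38 to 173.7 ± 4.92 TPM, and the lamin gene LMNB1 did not pass (log2 change 0.01, SE 0.05). BCL2 family genes rose in 16 and fell in 4 of 28 members and were not called (camera adjusted p = 0.067). BMF, BIK and BNIP3L rose by 1.03 to 1.44.

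**Figure D1:**
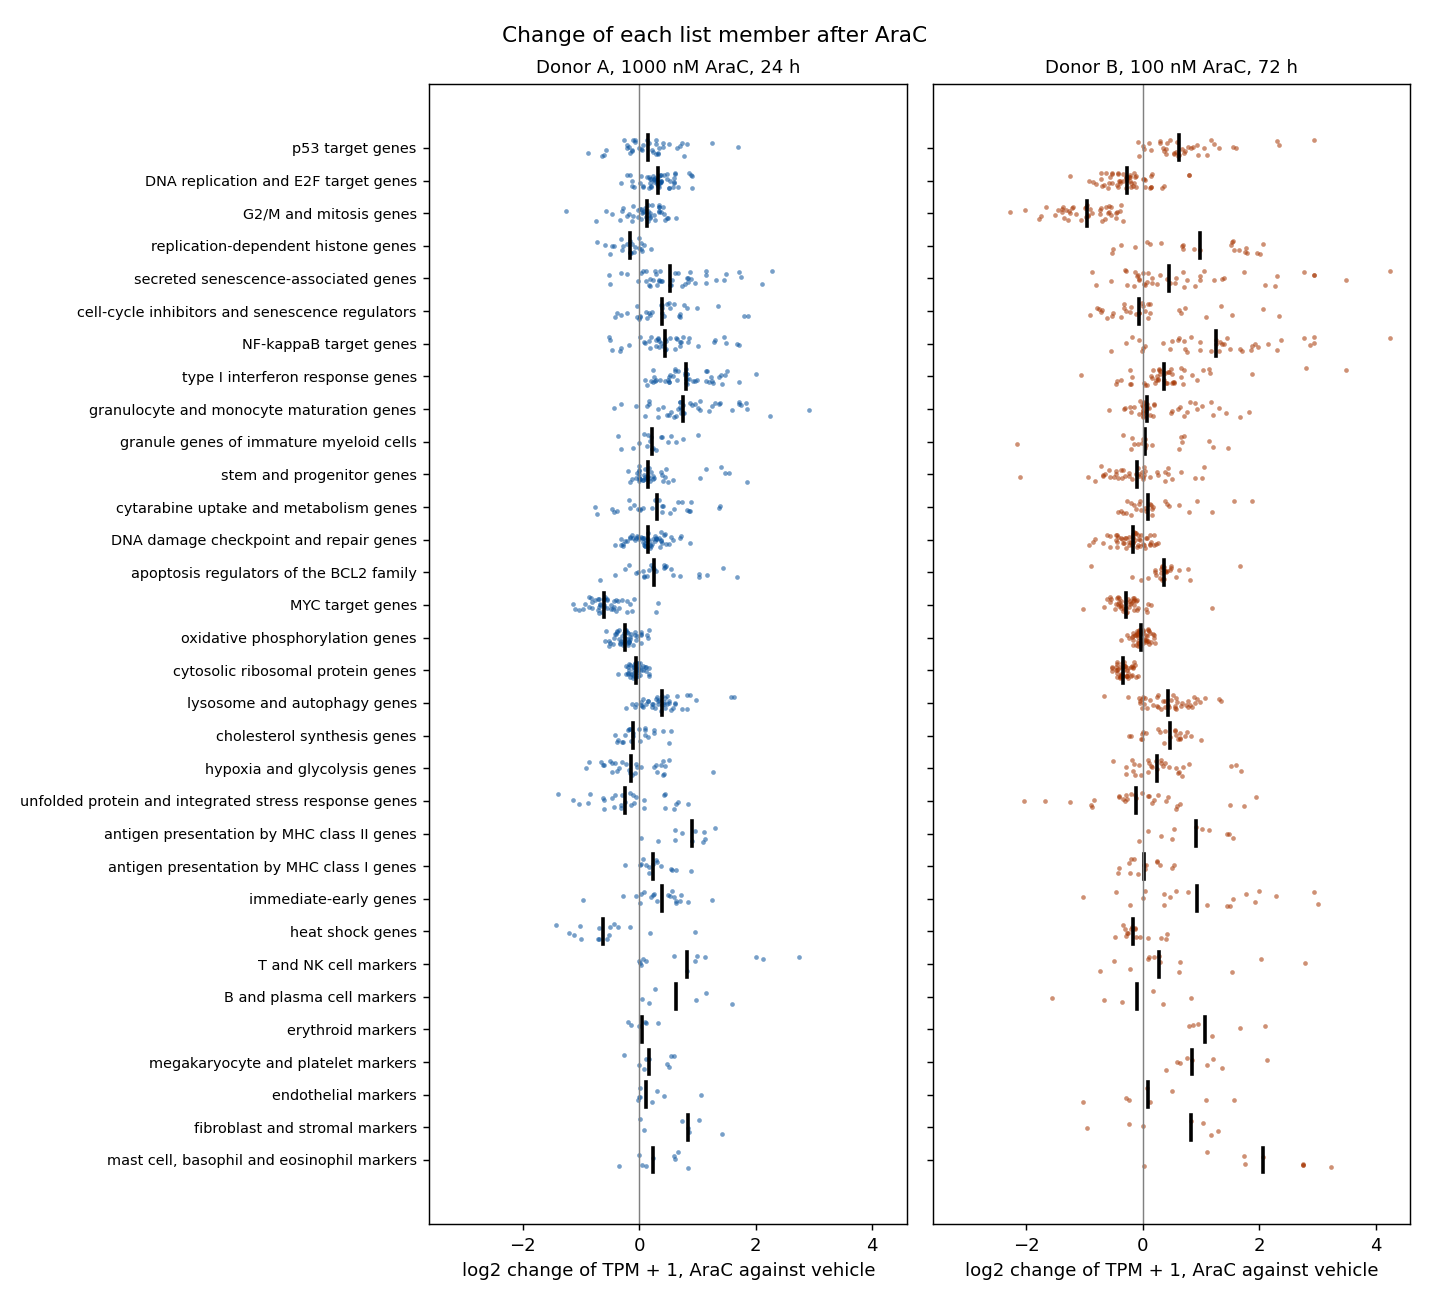
Each dot is 1 member gene of a list fixed before the data were examined, at its log2 change of TPM + 1 after AraC (x axis) in donor A (left, 3 against 3 libraries) and donor B (right, 2 against 2); black bars are list medians. G2/M genes have a median of 0.13 in donor A and -0.96 in donor B, and mast cell, basophil and eosinophil markers 0.24 and 2.07.

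In donor B the largest rise was in IL8. The neutrophil chemokine gene IL8 rose from 83.5 ± 0.581 to 1609 ± 255 TPM (mean ± SD, n = 2 each), a log2 change of 4.24 (SE 0.09), and complement C3 rose from 1.28 ± 0.0929 to 35.0 ± 0.0370 TPM. CXCL10, the prostaglandin D synthase gene HPGDS, the heme oxygenase gene HMOX1, the histamine-forming enzyme gene HDC, PVRL4, the lipoprotein gene APOE, MIR4635 and the immediate-early gene EGR1 rose by 3.01 to 3.49. The largest falls were in ASS1 (argininosuccinate synthase), from 74.0 ± 7.25 to 6.71 ± 0.932 TPM, PIF1, SOCS3, CDC20, CTSG, the receptor tyrosine kinase gene FLT3, PHGDH (the entry enzyme of serine synthesis), PLK1 (a mitotic kinase) and the short RNAs SNORD30 and SNORA81, by 1.97 to 3.28. Limma called 4257 genes higher and 2347 lower, 605 and 151 of them by at least 2-fold. The median gene was 0.08 higher, and the split was 3204 higher and 3393 lower with median-ratio scaling and 3371 higher and 3806 lower with quantile normalization. With 2 libraries per group, the estimate of the spread draws on donor A's libraries too.

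Mitosis genes fell and p53 target genes rose in donor B. Of 44 G2/M and mitosis genes 42 fell and none rose, with a median of -0.96. CDC20 fell from 99.5 ± 4.36 to 19.8 ± 0.0195 TPM, CCNB1 by 1.66 (SE 0.05), and the kinase gene AURKA and the centromere gene CENPA by 1.39 and 1.27 (camera adjusted p = 1.5e-29; adjusted p = 0.073 with an estimated correlation). Of 38 p53 target genes 31 rose (32 adjusted over the list alone) and none fell, with a median of 0.62. CDKN1A rose from 100.3 ± 1.62 to 513.8 ± 5.64 TPM (log2 change 2.35, SE 0.05), the stress cytokine gene GDF15 from 38.8 to 305 TPM, TP53INP1 by 2.30 (SE 0.11) and MDM2 from 43.9 ± 0.648 to 134.9 ± 3.44 TPM (camera adjusted p = 5.8e-10; adjusted p = 0.10 with an estimated correlation). Of 55 DNA replication and E2F target genes 34 fell and 4 rose. The helicase genes MCM2, MCM6 and MCM7 fell by 0.62 to 1.25, and RRM2 rose by 0.80 (SE 0.05) from 73.1 ± 3.22 to 127.6 ± 0.177 TPM (camera adjusted p = 4.8e-10; adjusted p = 0.19 with an estimated correlation). DNA damage checkpoint and repair genes fell in 23 and rose in 1 of 54 members, with CHEK1 and WEE1 down by 0.85 and 0.81 (camera adjusted p = 1.3e-06; adjusted p = 0.31 with an estimated correlation). Replication-dependent histone genes rose in 14 of 23 members and none fell (15 and 1 adjusted over the list alone), such as HIST1H1C from 33.9 to 109 TPM and HIST1H2BK from 45.5 to 155 TPM (camera adjusted p = 7.6e-04; adjusted p = 0.10 with an estimated correlation). The histone rise did not hold for the whole list. The members with log2 changes below 0, chosen after their values were seen, were HIST1H1B (-0.13), HIST1H3B (-0.38), HIST1H2BH (-0.50) and HIST2H2AC (-0.52). Whether the histone rise reflects DNA replication, or how the kit captures histone transcripts, was not tested. LMNB1 fell from 158.0 ± 4.58 to 93.7 ± 0.685 TPM, and GLB1 did not pass (log2 change -0.02, SE 0.05). MKI67 did not pass (-0.34, SE 0.25, adjusted p = 0.30), but passed in donor B's libraries alone (adjusted p = 0.0037) and without donor A vehicle replicate 2 (adjusted p = 0.035).

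Inflammatory genes rose in donor B. Of 41 NF-kappaB target genes 34 rose and 1 fell (2 adjusted over the list alone), with a median of 1.27. SQSTM1 rose from 214 to 535 TPM, and IER3 and EBI3 by 2.94 and 2.87 (camera adjusted p = 5.7e-11; adjusted p = 0.13 with an estimated correlation). Secreted senescence-associated genes rose in 24 (25 adjusted over the list alone) and fell in 5 of 44 members. SPP1, the osteopontin gene, rose by 2.28 (SE 0.10) and CCL5 by 1.06 (camera adjusted p = 0.0025; adjusted p = 0.37 with an estimated correlation). Immediate-early genes rose in 14 and fell in 2 of 20 members, with KLF6 from 114 to 438 TPM and BTG2 and NR4A2 up by 1.56 and 2.29 (camera adjusted p = 0.0018; adjusted p = 0.37 with an estimated correlation). Type I interferon response genes rose in 29 (30 adjusted over the list alone) and fell in 4 of 47 members, with LGALS3BP and CMPK2 up by 2.80 and 1.88 and IFITM1 down from 971 to 467 TPM (camera adjusted p = 0.0018; adjusted p = 0.23 with an estimated correlation). With median-ratio scaling 19 rose. Cell-cycle inhibitors and senescence regulators rose in 8 and fell in 13 of 32 members and were not called (camera adjusted p = 0.11). Their median was -0.06 and their mean 0.11. The members moved apart: log2 changes were 2.35 for CDKN1A and 1.53 for CDKN2A, but -0.75 for LMNB1, -0.71 for HMGB2 and -0.90 for TERT. A test for a single direction over this mixed list cannot be read as more or less senescence. BCL2 family genes rose in 22 (23 adjusted over the list alone) and fell in 1 of 28 members, the one that fell being the survival gene BCL2, by 0.88. BIRC3, PMAIP1 (NOXA) and BCL2L1 rose by 1.68, 0.81 and 0.57 (camera adjusted p = 1.9e-04; adjusted p = 0.13 with an estimated correlation). Lysosome and autophagy genes rose in 30 (31 adjusted over the list alone) and fell in 1 of 44 (camera adjusted p = 6.6e-06; adjusted p = 0.17 with an estimated correlation).

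Mast cell, basophil, megakaryocyte and erythroid genes rose in donor B. Of 9 mast cell, basophil and eosinophil markers 8 rose, with a median of 2.07. The tryptase gene TPSAB1 rose from 58.8 to 401 TPM, HDC from 10.6 ± 1.18 to 108.7 ± 5.17 TPM, PRG2, a granule protein of eosinophils and basophils, from 8.45 to 62.7 TPM and the transcription factor gene GATA1 from 37.9 to 131 TPM (camera adjusted p = 1.3e-06; adjusted p = 0.065 with an estimated correlation). All 9 megakaryocyte and platelet markers rose, including VWF from 51.8 to 230 TPM and ITGA2B from 149 to 387 TPM (camera adjusted p = 1.9e-04; adjusted p = 0.10 with an estimated correlation), as did all 6 erythroid markers, with HBD, ALAS2, EPOR and TFRC up by 0.86 to 1.67 (camera adjusted p = 4.9e-04; adjusted p = 0.073 with an estimated correlation). Of 11 MHC class II genes 9 rose, CD74 from 262 to 731 TPM among them (camera adjusted p = 4.9e-04; adjusted p = 0.073 with an estimated correlation). Granulocyte and monocyte maturation genes rose in 17 and fell in 2 of 43 members (camera adjusted p = 0.048; adjusted p = 0.18 with an estimated correlation), with ITGAM from 35.2 to 96.9 TPM and CD68 from 45.9 to 105 TPM. This call was also lost without donor B vehicle replicate 2 (adjusted p = 0.064) and with a pseudocount of 5 (adjusted p = 0.14). Granule genes of immature myeloid cells rose in 7 and fell in 2 of 19 members and were not called (camera adjusted p = 0.59). CTSG, a neutrophil protease gene, fell from 299 ± 11.3 to 66.3 ± 0.168 TPM and the granule proteoglycan gene SRGN rose by 1.47. Stem and progenitor genes fell in 18 and rose in 9 of 42 members (camera adjusted p = 0.0056; adjusted p = 0.32 with an estimated correlation). FLT3 fell from 12.6 ± 1.78 to 2.16 ± 0.428 TPM and the adhesion receptor gene GPR56 by 0.94, while EMP1 and TRIB2 rose by 0.90 and 1.06 and CD34 rose from 162.7 ± 8.85 to 231.1 ± 6.57 TPM. CEBPA rose by 0.80 (SE 0.07) from 5.43 ± 0.450 TPM.

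MYC target and ribosomal protein genes fell in donor B. Of 44 MYC target genes 25 fell (28 adjusted over the list alone) and 1, the transferrin receptor gene TFRC, rose. NAP1L1 and NOP56 fell by 0.56 each and MYC from 416 to 205 TPM (median -0.28, camera adjusted p = 4.5e-10; adjusted p = 0.10 with an estimated correlation). Of 44 cytosolic ribosomal protein genes 35 fell (36 adjusted over the list alone) and none rose, with a median of -0.33 (camera adjusted p = 1.9e-12; adjusted p = 0.31 with an estimated correlation), and with quantile normalization 23 fell and 1 rose. Heat shock genes fell in 7 (8 adjusted over the list alone) and rose in 3 of 16 members (camera adjusted p = 0.028; adjusted p = 0.17 with an estimated correlation), and this call was lost without donor B vehicle replicate 1 (adjusted p = 0.056) and with quantile normalization (adjusted p = 0.13). Oxidative phosphorylation genes fell in 5 of 49 members (2 adjusted over the list alone), none rose, and the list was not called (camera adjusted p = 0.051). With median-ratio scaling 6 fell and camera called the list down (adjusted p = 0.025). With quantile normalization 11 fell and 1 rose, without a call (adjusted p = 0.084).

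The list of cytarabine uptake and metabolism genes was not called by camera in either donor. In donor A 16 of 28 members rose and 5 fell (camera adjusted p = 0.21), and in donor B 10 rose and 6 fell (camera adjusted p = 0.67). The list shares TK1, RRM1, RRM2 and TYMS with the DNA replication and E2F list, so its counts do not describe the handling of AraC alone. With quantile normalization camera called the list up in donor A (adjusted p = 0.028), and fry called it up in donor A (adjusted p = 8.3e-07) and donor B (adjusted p = 9.2e-06). The balance in donor B turned with the scaling: 8 rose and 9 fell with median-ratio scaling, and 8 rose and 10 fell with quantile normalization. The deoxycytidine kinase gene DCK, whose product activates the drug, rose by 0.35 (SE 0.05) in donor A and fell by 0.27 (SE 0.06) in donor B, a difference of -0.62 (SE 0.08, limma adjusted p = 2.4e-04). SAMHD1, which hydrolyses the active triphosphate, rose from 78.6 ± 10.9 to 145.0 ± 4.29 TPM in donor A. In donor B it was at 4.48 TPM in vehicle and 5.12 TPM after AraC (difference -0.72, SE 0.15, limma adjusted p = 0.0043). CMPK2 rose in both, by 1.36 and 1.88, and the transporter gene ABCC4 rose in donor B from 34.4 to 104 TPM. ATR, the replication stress kinase gene, did not pass in either donor (log2 changes -0.21 and -0.05). In donor A it passed with median-ratio scaling (-0.32, adjusted p = 0.016), quantile normalization (-0.36, adjusted p = 0.0058) and without vehicle replicate 2 (-0.37, adjusted p = 0.0033).

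**Figure D2:**
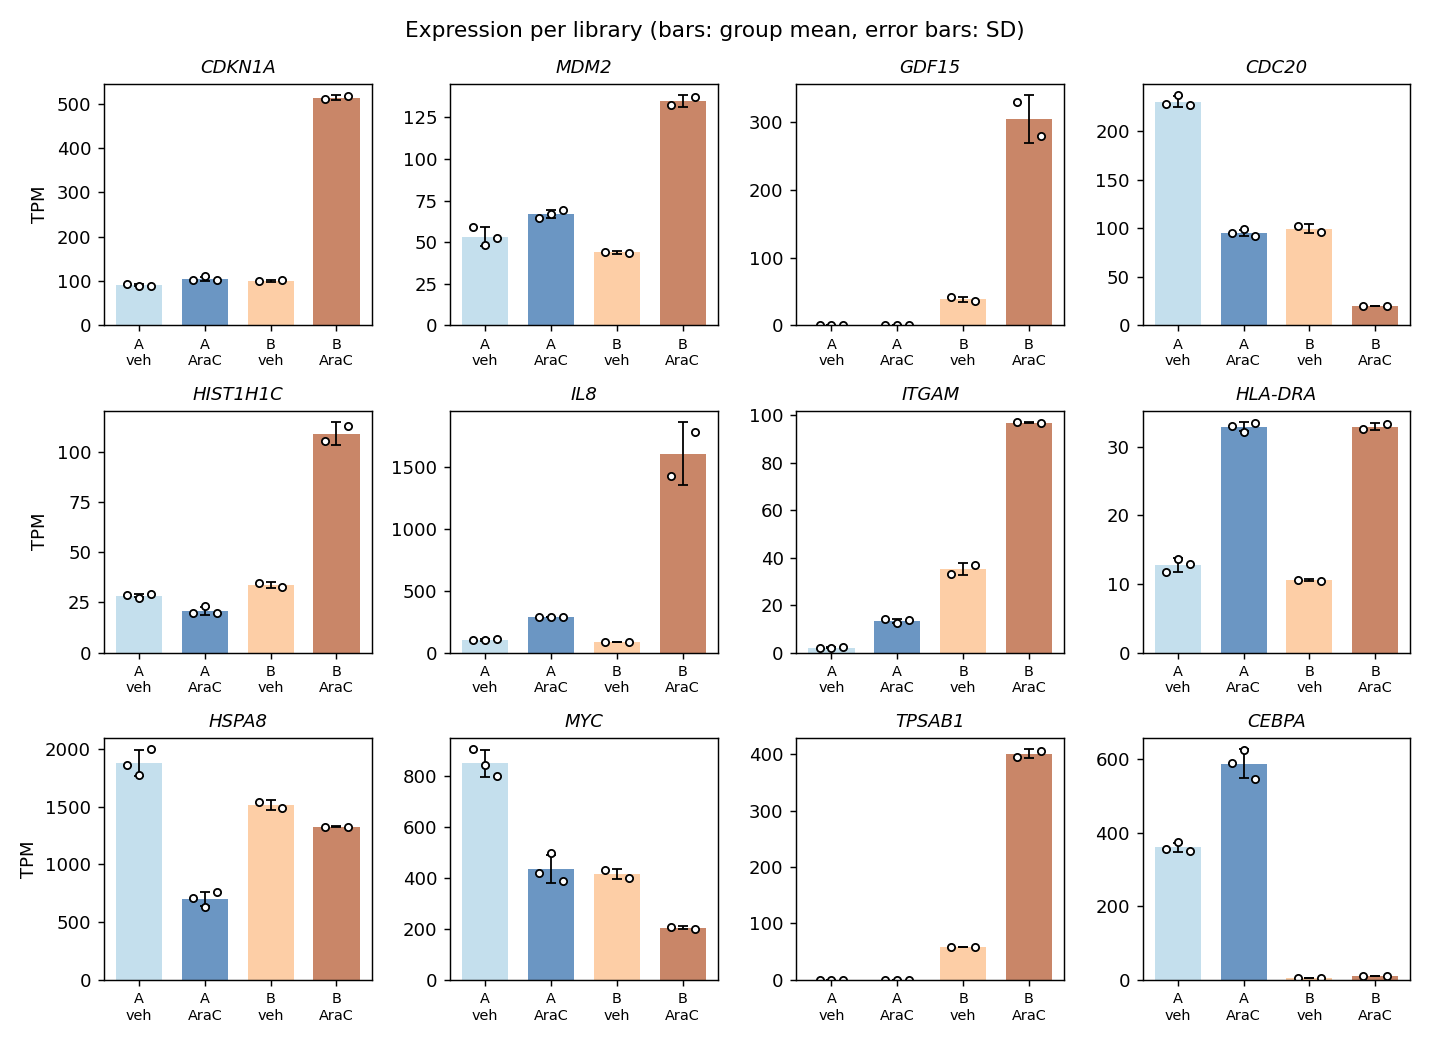
TPM (y axis, from 0) of 12 genes in each library (circles), with group means (bars) and SD (error bars), for vehicle (veh) and AraC in donor A (n = 3 per group) and donor B (n = 2 per group). CDKN1A lies near 100 TPM in 3 of the 4 groups and at 513.8 TPM after AraC in donor B, while HLA-DRA reaches 32.9 TPM after AraC in both donors.

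The responses of the donors shared a part and differed in much. Limma called 2101 genes higher in both donors, where 1638 would be called in both if the lists were independent, and 711 lower in both against 384; 741 genes were higher in donor A and lower in donor B, and 401 the reverse. Across the 14401 genes, which are not independent replicates, the changes of the donors correlated with Pearson's r of 0.228 and Spearman's rho of 0.220. The difference of the changes was called for 6539 genes, 3046 more positive in donor B and 3493 more negative. Lists called in the same direction in both donors were the secreted senescence-associated, NF-kappaB, interferon, granulocyte and monocyte, lysosome, MHC class II, MYC, ribosomal protein and heat shock lists. With an estimated correlation no list was called in donor B (lowest adjusted p = 0.065), so none of these 9 held in both donors. Of these, camera called no difference between donors for secreted senescence-associated genes (adjusted p = 0.76), lysosome and autophagy genes (adjusted p = 0.59) and MHC class II genes (adjusted p = 0.80). Their members still differed, in both directions. Of 44 secreted genes 17 were more positive and 15 more negative in donor B (18 and 16 adjusted over the list alone). The counts were 13 and 11 of 44 lysosome genes and 3 and 5 of 11 MHC class II genes (14 and 11, and 4 and 5, adjusted over the list alone). The missing calls are therefore no sign that the donors responded alike. Lists called up in one donor and down in the other were DNA replication and E2F targets (median difference -0.60, camera adjusted p = 9.6e-13; adjusted p = 0.17 with an estimated correlation), histones (median difference 1.46, camera adjusted p = 4.4e-06; adjusted p = 0.047 with an estimated correlation) and hypoxia and glycolysis genes (median difference 0.39, camera adjusted p = 2.4e-05; adjusted p = 0.046 with an estimated correlation). For p53 targets, 24 members were more positive in donor B and 4 more negative (28 and 4 adjusted over the list alone; camera adjusted p = 3.4e-07; adjusted p = 0.15 with an estimated correlation), and CDKN1A differed by 2.13 (SE 0.07). The donors differ in dose and time as well, so the effects of donor, dose and time cannot be told apart.

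**Figure D3:**
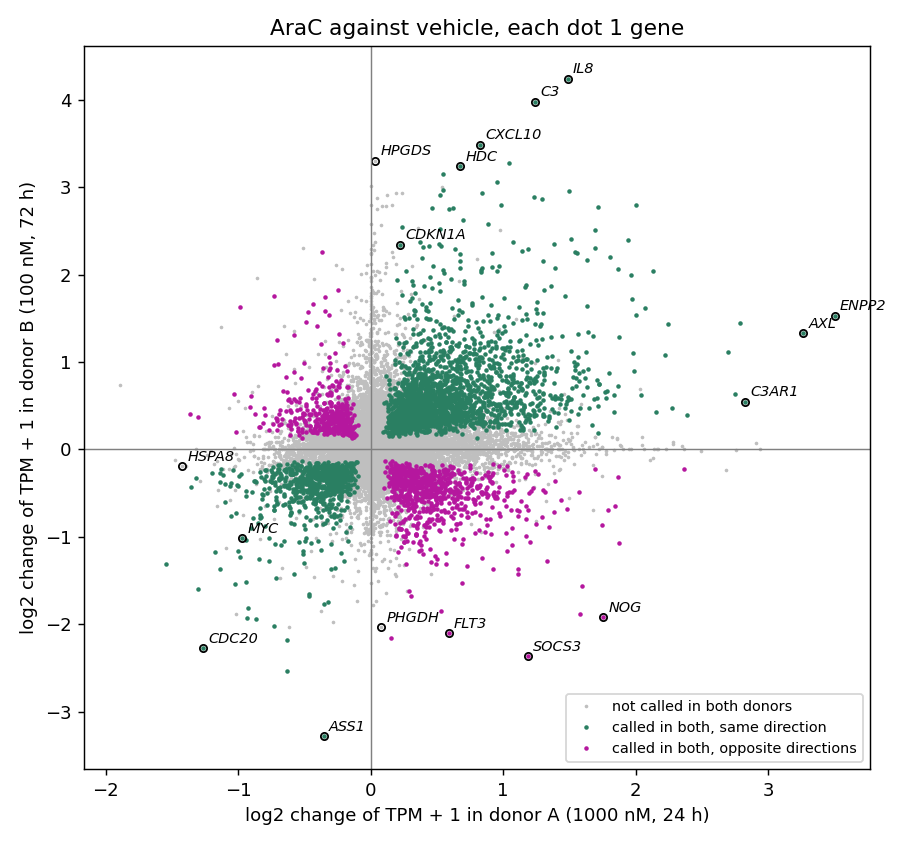
Each dot is 1 of 14401 genes at its log2 change of TPM + 1 after AraC in donor A (x axis) and donor B (y axis); green and magenta dots were called in both donors in the same (2812 genes) or in opposite directions, and circled genes are labelled. IL8 lies at 1.49 and 4.24, and SOCS3 at 1.19 and -2.37.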

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

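What is listed here is what a test of the difference between donors (donor B minus donor A) singled out. Limma called such a difference for 6539 genes. By camera, 21 lists differed. Of these, 12 were more positive in donor B, with these median log2 differences: p53 target genes 0.53, replication-dependent histone genes 1.46, NF-kappaB target genes 0.85, MYC target genes 0.28, oxidative phosphorylation genes 0.21, cholesterol synthesis genes 0.52, hypoxia and glycolysis genes 0.39, immediate-early genes 0.26, heat shock genes 0.64, erythroid markers 1.04, megakaryocyte and platelet markers 0.64, and mast cell, basophil and eosinophil markers 2.09. Several mast cell and erythroid markers were near the floor in donor A (mean TPM in vehicle and after AraC 0.118 and 0.159 for TPSAB1, 0.0287 and 0.0326 for CPA3, 0.0331 and 0.115 for ALAS2), where log2(TPM + 1) holds a change near 0, so these differences say little about donor A. The other 9 were more negative: DNA replication and E2F target genes -0.60, G2/M and mitosis genes -1.08, cell-cycle inhibitors and senescence regulators -0.44, type I interferon response genes -0.41, granulocyte and monocyte maturation genes -0.41, stem and progenitor genes -0.25, DNA damage checkpoint and repair genes -0.36, cytosolic ribosomal protein genes -0.24, and B and plasma cell markers -0.67. With the correlation estimated per list, 5 of the 21 differed: histones, granulocyte and monocyte maturation, hypoxia and glycolysis, erythroid markers and mast cell markers. The calls for these lists were also lost: granulocyte and monocyte maturation genes with voom (adjusted p = 0.40), megakaryocyte markers with a pseudocount of 0.1 (adjusted p = 0.16) and with voom (adjusted p = 0.65), oxidative phosphorylation genes with quantile normalization (adjusted p = 0.096), and B and plasma cell markers with a filter of 5 TPM (adjusted p = 0.080), with quantile normalization (adjusted p = 0.050) and when any 1 of 3 of the vehicle libraries was left out. The genes with the most positive differences were HPGDS (3.27), MIR4635 (3.02), CXCL2 (2.83), LOC645638 (2.82) and SCGN (2.79). The most negative were NOG (-3.67), SOCS3 (-3.55), HOPX (-3.46), MZB1 (-3.16) and TDRD9 (-2.95).

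More genes were higher than lower after AraC in both donors (70.1% of called genes in donor A and 64.5% in donor B). With median-ratio scaling 56.1% were higher in donor A, and 48.6% in donor B. This scaling centres the median change and so moves the share toward 50% by construction, which leaves library composition open in both donors. Gene length, known here only as a relative length inferred from the read steps of the TPM values, went with part of the pattern in donor A, where 57.8%, 69.7% and 83.3% were higher among the shortest, middle and longest genes (Spearman's rho of change and length 0.156), and less in donor B (61.1%, 64.8% and 67.7%). As most called genes were higher even among the shortest, length alone was not the whole cause. Among called genes at a mean of 20 TPM or more, 59.9% in donor A and 58.6% in donor B were higher. These shares lay below those over all called genes, so genes with lower values were more often higher and added to the pattern. Whether the detection floor itself caused this cannot be told from these shares. The design gives no measure of total RNA per cell, and no biological explanation was tested.

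Mast cell, basophil and eosinophil markers were higher after AraC in donor B. A loss of the main cell type would raise the markers of other cells alike, if those cells were present and measurable in donor B. Against 2.07, the largest median among T and NK cell, B and plasma cell and endothelial markers was 0.27, a test chosen after the result was seen. Members needed a TPM of 1 in only 2 of the 10 libraries, so they could be near 0 in donor B. There log2(TPM + 1) holds a change near 0, so this test cannot tell. Lists outside that test lay between (erythroid 1.07, megakaryocyte and platelet 0.84, fibroblast and stromal 0.84), so the markers moved apart, but the mast cell markers were not alone in rising. No single library made the pattern, as the lowest median without 1 donor B library was 2.05. A larger share of cells of this lineage would change its own transcripts by 1 factor; the SD of the 8 members' changes was 0.72 against a median standard error of 0.24, which cannot tell, since other cells in the culture may express them. A loss of the main cell type, induction within the cells and a larger share of this lineage cannot be told apart here.

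The p53 target genes were higher after AraC in donor B and less in donor A, where fry called them up (adjusted p = 0.0055) and camera did not (adjusted p = 0.99). In donor A 54.8% of tested genes were called between its groups, a test chosen after the result was seen; exchanged labels, or a group difference other than treatment, would give the same value. The overlap with donor B runs the way the labels say (2101 genes higher in both against 1638 expected, 711 lower in both against 384, and in opposite directions 741 against 903 and 401 against 697), which speaks against an exchange in donor A if the donors share a response; that was not tested, and a group difference other than treatment stays open. The median standard error of these genes in donor A was 0.069. For the typical member, the spread between these libraries was thus too small to hide a change like donor B's median of 0.62. That spread may be technical, so precision between separate cultures stays open. Members near the floor are not covered either: GDF15 lay at 0 to 0.41 TPM in donor A, where log2(TPM + 1) holds a change near 0. No single library made the difference, whose largest adjusted p without 1 library was 7.3e-07 by camera with the preset correlation; with an estimated correlation the call was lost with all libraries (adjusted p = 0.15). Dose, time and donor also remain as explanations and cannot be told apart.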

How the results depend on the processing

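Of the values for named genes, 6548 stayed on their side of the threshold under an alternative, 87 were no longer called, 7 became called and 1 reversed; of those for lists, 2230 stayed, 88 were lost, 45 gained and 3 reversed. Direction was compared only where a call was made with or without the alternative, and lists without a call also turned, such as p53 target genes in donor A with median-ratio scaling (up to down by camera). Requiring a change of at least 2-fold left 638 genes higher and 50 lower in donor A, 605 and 151 in donor B, 1102 that differed between donors and 101 that changed the same way. Quantile normalization called 4213 genes lower in donor A and 3806 in donor B. An estimated correlation left 4 lists called in donor A, 0 in donor B and 5 between donors, and fry called 28 in donor A. Reversed were, with quantile normalization, cytosolic ribosomal protein genes in donor A (median 0.00012) and ESAM in donor A (-0.11), both without a call. With fry, cell-cycle inhibitors and senescence regulators in donor B (median -0.058) and endothelial markers between donors (-0.34) took the other direction; fry compares with 0 and camera with other genes. Otherwise the cause was not tested.

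Leaving out each library in turn gave 4779 to 5935 genes higher and 2044 to 2668 lower in donor A, 2909 to 4757 higher and 1649 to 2694 lower in donor B, 4981 to 7080 that differed between donors and 2000 to 3024 that changed the same way, and 16 to 17, 20 to 22 and 20 to 22 lists. Where this left 1 library in a group of donor B, that library was assumed to vary like the others. With the replicate number as a replicate block, 5089 genes were higher and 2134 lower in donor A, 3768 and 2015 in donor B, 5668 differed between donors and 2362 changed the same way, with 17, 20 and 21 lists. Same-numbered libraries showed no common deviation from their group means (correlations of -0.18, -0.05 and 0.19 in donor A and 0.03 and 0.03 in donor B). Deviations from a group mean cancel within the group, and in donor B both values are the same by construction. These correlations give no sign of pairing but cannot exclude it.

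Of the 10 ways to split donor A's 6 libraries into groups of 3, only 1, the real one, called 7898 genes, and the others called 0 to 1. For lists, 2 of the 10 called as many as the real split, 17. With 10 splits no p under 0.1 is possible. Every other split also mixes vehicle and AraC libraries in both groups, which moves the treatment difference into the spread tested against. Few gene calls there follow from this design, so the splits cannot tell whether the real grouping arose by chance. Median-ratio and quantile scaling moved the share of genes that are higher, as the report gives, and voom and leaving out small RNA genes were chosen after seeing the data.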

Other observations

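Of 23 cholesterol synthesis genes 16 rose and 2 fell in donor B, including DHCR7 with a rise of 0.83. Camera called the list up there (adjusted p = 0.0028), and the call was lost with an estimated correlation (adjusted p = 0.22). In donor A 5 rose and 6 fell, without a call (camera adjusted p = 0.085). With median-ratio scaling 3 rose and 11 fell in donor A, and camera called the list down (adjusted p = 0.038). Quantile normalization gave no call there (adjusted p = 0.79). Of 30 hypoxia and glycolysis genes 14 fell (15 adjusted over the list alone) and 10 rose in donor A (camera adjusted p = 0.0044; adjusted p = 0.080 with an estimated correlation), where LDHA fell by 0.86 and the glucose transporter gene SLC2A1 by 0.91 and NDRG1 rose by 1.26. In donor B 17 rose and 3 fell (camera adjusted p = 0.048; adjusted p = 0.17 with an estimated correlation), with the lactate transporter gene SLC16A3 up by 1.70; this call was lost with median-ratio scaling (adjusted p = 0.088) and in donor B's libraries alone (adjusted p = 0.11). Of 29 unfolded protein and integrated stress response genes 16 fell and 7 rose in donor A (17 and 9 adjusted over the list alone; camera adjusted p = 5.4e-05; adjusted p = 0.23 with an estimated correlation), among them the amino acid transporter gene SLC7A5, which fell by 1.13, and ASNS, which fell by 0.84. In donor B 10 rose and 12 fell (adjusted p = 0.057). There the serine synthesis genes PHGDH and PSAT1 fell by 2.04 and 1.68 and SHMT2 by 0.89, and PPP1R15A rose by 1.95.

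Markers of other cells changed as well. Of 13 T and NK cell markers 8 rose in donor A (camera adjusted p = 0.012; adjusted p = 0.12 with an estimated correlation), with GZMA up by 2.13, and 6 rose and 1 fell in donor B (adjusted p = 0.11). Of 7 fibroblast and stromal markers 5 rose in donor A (camera adjusted p = 0.031; adjusted p = 0.39 with an estimated correlation), with SPARC up by 0.85 and FN1 by 1.42, and 4 rose and 1 fell in donor B (adjusted p = 0.34). B and plasma cell markers rose in 3 of 6 in donor A (camera adjusted p = 0.085) and rose in 2 and fell in 2 in donor B (2 and 3 adjusted over the list alone; adjusted p = 0.36), where MZB1 fell by 1.56 after a rise of 1.60 in donor A. Endothelial markers rose in 4 of 8 in donor A (3 adjusted over the list alone; camera adjusted p = 0.46) and rose in 3 and fell in 2 in donor B (adjusted p = 0.68). In donor A, erythroid markers (1 of 6 rose and 1 fell, camera adjusted p = 0.56), megakaryocyte and platelet markers (4 of 9 rose and 1 fell, adjusted p = 0.56) and mast cell, basophil and eosinophil markers (5 of 9 rose and 1 fell, adjusted p = 0.43) were not called, nor were immediate-early genes (10 of 20 rose and 2 fell, adjusted p = 0.23). MHC class I genes in donor B rose in 5 and fell in 3 of 15 (camera adjusted p = 0.63). This balance turned with the scaling: 1 rose and 4 fell with median-ratio scaling, and 3 rose and 6 fell with quantile normalization.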
